A study of Homo sapiens with 18 samples.

How the data were processed

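Expression was measured with 18 Affymetrix arrays of LNCaP cells, 3 for each of 6 groups of virus and stimulus. Each deposited value is a log2 signal of a probe set, made by the authors with RMA, as the submitters' processing notes name it without a version. The values ran like RMA output on a log2 scale, and array medians lay between 6.32 and 6.38. Which steps beyond RMA were applied between arrays stays unknown, since the quantiles of the arrays lay close together without being identical. No value was rescaled. Signal, background and detection calls were not in the table, so precision is stated only as limited by the number of arrays.

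Of 54675 probe sets, 41097 carried 1 gene symbol, 1801 several and 11777 none. Control probe sets were removed, and symbols were matched to the gene reference by Entrez identifier for 41037 probe sets. Each gene was represented by the probe set with the highest mean over all 18 arrays, which gave 19775 genes. Probe sets with several symbols or none were left out of the gene tests, because they cannot be assigned to 1 gene, and no filter on dim genes was used.

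A linear model with 1 mean per group was fitted to all 18 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 12 residual and 6.015 prior degrees of freedom. P values were two-sided and adjusted by the Benjamini-Hochberg method over all genes within each of 13 contrasts, with a threshold of 0.05. The contrasts were DHT against ethanol within each virus, each cyclin against GFP and both cyclins against each other within each stimulus, the 3 differences between DHT responses, and the mean DHT response. The replicate number was not a block. Arrays with the same number deviated together between GFP in ethanol and GFP in DHT (correlations across genes of 0.662, 0.428 and 0.520) and between GFP and cyclin D1b in DHT (0.149, 0.153 and 0.113), and in no other compared pair of groups did all 3 correlations exceed 0.1, the bound used for pairing. Values with the number as a block over all viruses are therefore given for those comparisons (75 and 6870 changed genes). Between ethanol and DHT within the cyclin cells such correlations were at most 0.0198, so that block does not isolate a pairing within GFP cells. A count with a block within each virus is given with the results. Deviations within a group cancel out, so GFP replicate 1 standing apart in both stimuli also raises the correlations of replicates 2 and 3.

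The comparisons, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. For DHT in GFP cells and each cyclin against GFP, the rule names the 8 largest rises and the 8 largest falls among genes past the threshold whose groups did not overlap. For the other comparisons it names 5 in each direction, and where no gene passed the 3 with the smallest p. It adds up to 4 members with the smallest p of any list described, and CCND1, SNAI2, AR, KLK3, TMPRSS2 and FKBP5 in every case. AR is not analysed here.

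The 22 lists were androgen-induced genes, androgen-repressed genes, S phase and replication, mitosis, G1 cell cycle regulators, interferon response, NF-kB and inflammation, mesenchymal genes, epithelial junctions, invasion and adhesion, cholesterol synthesis, fatty acid synthesis, secretory protein folding, the amino acid response of ATF4, p53 targets, heat shock, ribosome biogenesis, hypoxia and glycolysis, and markers of neuroendocrine cells, basal epithelium, stroma, and leukocytes and endothelium. They were tested by camera with a preset correlation between genes of 0.01, adjusted over the lists within a contrast, and again with an estimated correlation. The fry test was a further check: its p asks whether a list's genes move, on balance, in 1 direction, without comparing them with other genes.

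The number of lists called by camera, and of those also called with an estimated correlation, was 8 and 1 for DHT in GFP cells, 8 and 0 in cyclin D1a cells and 11 and 4 in cyclin D1b cells. It was 10 and 7 for cyclin D1a and 10 and 0 for cyclin D1b against GFP in ethanol, and 10 and 5 and 10 and 3 in DHT. For both cyclins against each other it was 9 and 2 in ethanol and 10 and 3 in DHT.

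Spread of a list median in the tests of explanations was the SE over its genes (2000 bootstrap draws), which holds no spread between arrays, and the jackknife SE over arrays. The latter was added after the data had been seen. Overlaps of both cyclins were compared with 100 simulations of unchanged groups sharing the GFP arrays. The alternatives covered every probe set, the mean of a gene's probe sets, the upper part of genes by mean, quantile normalization again, median centring, a replicate block, only the groups compared, trend and robust variance, each array left out, both GFP replicate 1 arrays left out, and a threshold of 0.01 for overlaps. Blocks within each virus, the label number set as a term, and GFP replicate 1 as the only GFP arm were added after the data had been seen. In that last setting the lone array is assumed to vary like the other groups.

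The code was tested on simulated data with 200 changed genes per comparison. For cyclin D1a against GFP it called 0.702 of genes changed by 0.5 on the log2 scale and 0.955 of those changed by 1, and 0.0684 of its calls were false. For the difference between DHT responses the shares called were 0.209 and 0.881, with 0.0282 false. A list with a planted change was found, and camera called 0 of the unchanged lists. The simulated genes varied independently of each other, so this cannot show how often correlated genes give false list calls. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.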

Results

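RNA was profiled from LNCaP cells, an androgen-sensitive line of human prostate adenocarcinoma, on 18 Affymetrix 1-colour arrays. The cells had been kept for 72 h in medium with 5% charcoal-dextran treated serum, which lowers steroid hormones. They then received a virus encoding GFP, cyclin D1a (the full-length product of CCND1) or cyclin D1b (its splice variant) for 24 h, and either 1 nM dihydrotestosterone (DHT) or 0.01% ethanol for 16 h. The 6 groups of virus and stimulus held 3 arrays each, which the series text calls a biological triplicate without saying whether the cultures were separate transductions. Array medians lay between 6.32 and 6.38 on the log2 scale, and 19775 genes were tested. Error is the standard error of the fitted log2 difference with n = 3 arrays per group, unless another spread is named, and precision is limited by the number of arrays. Without detection calls, a difference from a level below the array medians is one of signal, and its size in transcript is not known here. The table gives no genomic positions for its probe sets, and AR, the androgen receptor gene, is not analysed here. The sample labels carry numbers: GFP replicate 1 in both stimuli and all 6 cyclin D1b arrays were numbered below 125, and the other 4 GFP arrays and all 6 cyclin D1a arrays from 125 on. The labels do not say what the numbers mean, and the border at 125 was drawn here. GFP replicate 1 carried 106 and 101, the cyclin D1b arrays carried 118 to 124, and those of GFP replicate 2 carried 125 and 126. Both GFP replicate 1 arrays stood apart from the other GFP arrays on the second principal component (18.2% of variance), at -40.5 and -33.4 against -16.6 to -13.7. Their mean 3' minus 5' difference over the GAPDH and ACTB control probes, a measure of RNA integrity, was 0.764 and 0.706. It was 0.171 to 0.519 in the other 4 GFP arrays, 0.0665 to 0.216 in the cyclin D1a arrays and 0.291 to 0.812 in the cyclin D1b arrays. Values within each set of numbers are therefore given beside the pooled ones.

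The response to DHT in GFP cells gave the reference for androgen signalling in this line. KLK3, which encodes prostate-specific antigen, rose from a mean of 11.90 ± 0.128 to 13.01 ± 0.295 (SD, n = 3), a log2 fold change of 1.11 ± 0.119 (adjusted p = 0.000389). Its neighbour KLK2, another secreted kallikrein protease, rose by 1.43 ± 0.158, and TRPM8, a cold-sensing cation channel, by 1.44 ± 0.215. Genes of DNA replication rose too, among them CDC6 (which licenses replication origins) at 1.16 ± 0.171 and DTL (an adaptor of a ubiquitin ligase) at 1.04 ± 0.16. So did UHRF1 (which maintains DNA methylation) at 0.98 ± 0.138 and RRM2 (a subunit of ribonucleotide reductase) at 0.56 ± 0.0979. Coagulation factor F5 rose by 1.14 ± 0.244 (adjusted p = 0.0478) and the fatty acid elongase ELOVL7 by 1.00 ± 0.149. SNAI2, which encodes the transcription factor Slug, rose by 0.90 ± 0.134 (adjusted p = 0.00482). The largest falls were in DAB1, an adaptor of reelin signalling (-1.20 ± 0.25, adjusted p = 0.0438), MAN1A1, a Golgi mannosidase (-0.93 ± 0.188), and SI, sucrase-isomaltase (-0.79 ± 0.13). Others were in HS6ST2, a heparan sulfate sulfotransferase (-0.77 ± 0.143), and COL5A2, a collagen chain (-0.70 ± 0.15). HOXC9, a homeobox factor, fell by 0.63, SLC44A1, a choline transporter, by 0.61, and PLEKHA2, a phosphoinositide-binding protein, by 0.61. The androgen-induced genes TMPRSS2, a membrane serine protease (0.33 ± 0.223, adjusted p = 0.707), and FKBP5, a co-chaperone of steroid receptors (0.59 ± 0.177, adjusted p = 0.184), did not pass, nor did CCND1 (-0.02 ± 0.175). TMPRSS2 and FKBP5 each passed in at least 1 of the alternatives. Of 45 S phase genes 8 rose and none fell (34 rose when adjusted over the list alone; median 0.39), with a camera adjusted p of 8.29e-39 and adjusted p = 0.0243 with an estimated correlation. Of 37 androgen-induced genes 6 rose and 1 fell (15 and 2 adjusted over the list alone; median 0.32), and that list's call was lost at adjusted p = 0.0877 with an estimated correlation. Cholesterol synthesis genes had a median of 0.23 with no member passing over all genes and 10 of 19 passing when adjusted over the list alone (adjusted p = 0.0726 with an estimated correlation). In all, limma called 87 genes, 32 up and 55 down, 32 of them by at least 1.5-fold. In the pair of replicate 1 alone, the androgen-induced median was 0.61 and the S phase median 0.63, against 0.14 and 0.29 in replicates 2 and 3. In that pair F5 rose by 2.08, against 0.67 in the others, CDC6 by 1.93 against 0.77, DTL by 1.76 against 0.68, FKBP5 by 1.30 against 0.24 and TMPRSS2 by 0.64 against 0.18. HOXC9 was at -1.11 against -0.40 and CCND1 at 0.32 against -0.19. The count was 352 genes with replicate 1 as the only GFP pair, 169 without it, 75 with the replicate number as a block over all viruses and 280 with a block within each virus, which was chosen after the data were seen. With the block over all viruses the 8 list calls were kept. It was 248 without the ethanol array of replicate 1 alone, 47 without that of replicate 3 and 36 without the DHT array of replicate 2. It was 0 by limma fitted to the 6 GFP arrays alone (990 at an unadjusted p under 0.05). F5 lost its call with the block over all viruses (adjusted p = 0.0555, and 1.76e-05 to 0.879 over all alternatives) and kept it with the block within each virus (0.0246). With the mean of a gene's probe sets the calls of F5 (0.47), DAB1 (-0.64), MAN1A1 (-0.63) and COL5A2 (-0.61) were lost (adjusted p = 0.0534 to 0.328). With trend and robust variance those of F5 and DAB1 were lost (0.0817 and 0.0739). DAB1 lost its call (adjusted p = 0.126) without the DHT array of replicate 3, F5 and COL5A2 (0.133 and 0.13) without the ethanol array of replicate 2. MAN1A1 lost it (0.12) without that of replicate 3, and HOXC9 and HS6ST2 (0.113 and 0.0511) without the DHT array of replicate 2.

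In cyclin D1a cells, KLK3 rose with DHT from 10.88 ± 0.026 to 12.14 ± 0.18 (SD, n = 3), by 1.25 ± 0.119 (adjusted p = 7.76e-05), and KLK2 by 1.24 ± 0.158 (adjusted p = 0.00291). These were the 2 genes that limma called there, with 720 genes at an unadjusted p under 0.05, and the same 2 were called without each of the 6 arrays in turn. TRPM8 had a value of 1.20 ± 0.215 and missed the threshold (adjusted p = 0.173). SNAI2 (-0.02 ± 0.134), FKBP5 (0.20 ± 0.177), TMPRSS2 (0.24 ± 0.223) and CCND1 (-0.15 ± 0.175) did not pass. The androgen-induced list had a median of 0.18, with 2 of 37 members rising (4 adjusted over the list alone), and the S phase list a median of 0.12 with none of 45 passing either way. Both list calls were lost, each at adjusted p = 0.367 with an estimated correlation.

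Cyclin D1b cells gave the largest count of DHT responses, 1161 genes by limma, 883 up and 278 down, of which 325 changed by at least 1.5-fold. The noncoding RNA LINC00844 rose by 3.33 ± 0.657 (adjusted p = 0.0045) and F5 by 2.43 ± 0.244, from 5.78 ± 0.116 to 8.20 ± 0.0855 (SD, n = 3). TRPM8 rose by 2.00 ± 0.215, AZGP1, a secreted zinc-binding glycoprotein, by 1.98 ± 0.165, and EAF2, a transcription elongation cofactor, by 1.90 ± 0.229. KLK3 rose by 1.61 ± 0.119 (adjusted p = 1.36e-06), FKBP5 by 1.69 ± 0.177 (adjusted p = 1.78e-05), TMPRSS2 by 1.09 ± 0.223 (adjusted p = 0.00596) and SNAI2 by 0.48 ± 0.134 (adjusted p = 0.04), while CCND1 did not pass (0.20 ± 0.175). Falls were led by DAB1 (-1.31 ± 0.25), ABCA1, the cholesterol efflux pump (-1.26 ± 0.279), HS6ST2 (-0.99 ± 0.143), MATN2, a matrix protein (-0.95 ± 0.145), and GUSBP1, a pseudogene of beta-glucuronidase (-0.91 ± 0.152). Of 37 androgen-induced genes 26 rose and 1 fell (28 and 1 adjusted over the list alone; median 0.73), among them CENPN (a centromere protein) at 1.58 and KLK2 at 1.73. Among 45 S phase genes 35 rose (41 adjusted over the list alone; median 0.60), with RRM2 at 0.99 and the helicase subunit MCM5 at 1.22. Of 19 cholesterol synthesis genes 12 rose (14 adjusted over the list alone; median 0.44), including EBP at 0.84 and HMGCS1 at 0.86. These 3 lists kept their camera calls with an estimated correlation (adjusted p = 0.0157, 0.0109 and 0.0109), as did the androgen-repressed list (0.0109). In the latter UGT2B17 and UGT2B15, enzymes that glucuronidate androgens, fell by 0.84 and 0.89 and 3 of 12 fell (4 adjusted over the list alone). Mitosis genes rose in 20 of 36 cases (22 adjusted over the list alone; median 0.47), with TTK, a spindle checkpoint kinase, at 1.24, and that list's call was lost at adjusted p = 0.142 with an estimated correlation. All 6 arrays belong to the set of numbers below 125. The count was 635 without the ethanol array of replicate 2, 567 without that of replicate 3, 635 without the DHT array of replicate 1 and 699 without that of replicate 3. SNAI2 lost its call (adjusted p = 0.0637 to 0.152) without any 1 of those 4 arrays or the DHT array of replicate 2, and ABCA1 (0.0523) without the DHT array of replicate 1.

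**Figure D1:**
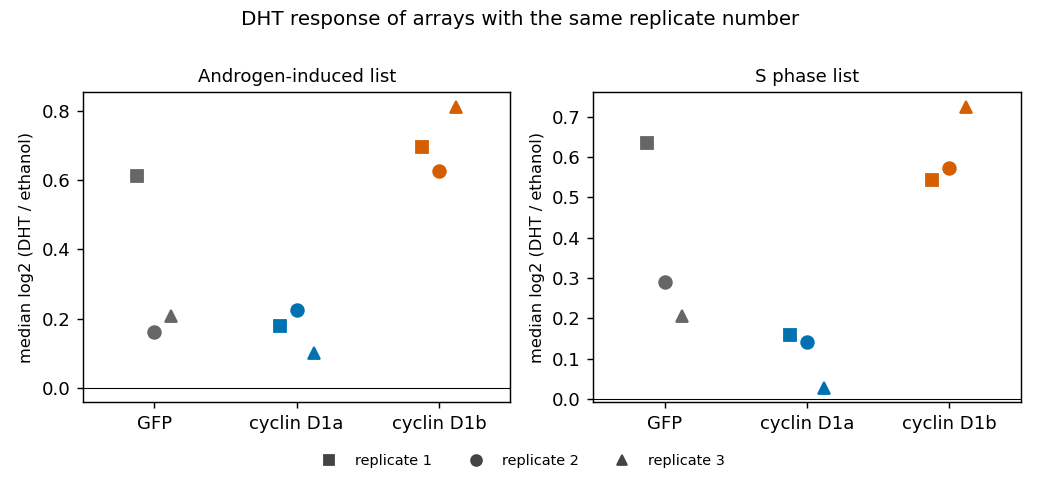
Median log2 ratio of DHT to ethanol over the androgen-induced list (37 genes) and the S phase list (45 genes), for each pair of arrays that share a virus and a replicate number. The androgen-induced medians were 0.613, 0.162 and 0.206 in GFP cells, 0.180, 0.226 and 0.102 in cyclin D1a cells and 0.694, 0.627 and 0.812 in cyclin D1b cells.

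Whether a cyclin changed the response to DHT was tested by the difference between responses. Between cyclin D1b and GFP cells, 5 genes differed, all with the larger response in cyclin D1b cells. They were RNF182, a ubiquitin ligase (1.08 ± 0.159), GPER1, a membrane estrogen receptor (1.01 ± 0.154), OTULINL (0.99 ± 0.144), LSM11, a factor in histone mRNA processing (0.92 ± 0.138), and PRCP, a carboxypeptidase (0.84 ± 0.141, adjusted p = 0.0489). FKBP5 differed by 1.09 ± 0.251 without passing (adjusted p = 0.17), and KLK3 (0.50 ± 0.168), TMPRSS2 (0.76 ± 0.315), SNAI2 (-0.42 ± 0.189) and CCND1 (0.23 ± 0.247) did not pass either. FKBP5, KLK3 and TMPRSS2 did pass in some alternatives (lowest adjusted p = 1.51e-05, 0.0149 and 0.000538). Their DHT responses in cyclin D1b cells were 1.69, 1.61 and 1.09, against 0.24, 0.92 and 0.18 in GFP replicates 2 and 3. With the mean of a gene's probe sets LSM11 (0.25, adjusted p = 0.396) and PRCP (0.26, adjusted p = 0.571) lost their calls. PRCP also lost it with the replicate block (0.0673), quantile normalization again (0.0856) and median centring (0.0513), and GPER1 with quantile normalization again (0.0594). Over all alternatives the adjusted p ranged from 0.0025 to 0.396 for LSM11, from 0.000538 to 0.571 for PRCP and from 0.00321 to 0.187 for GPER1. The androgen-induced list responded more in cyclin D1b cells by a median of 0.39 (no member over all genes, 15 of 37 adjusted over the list alone), and the camera call was lost at adjusted p = 0.344 with an estimated correlation. Against the GFP pair of replicate 1 alone, numbered in the same set, that median was 0.16 and the S phase difference was -0.0010 against 0.28 pooled. There FKBP5 was at 0.39, KLK3 at 0.099, TMPRSS2 at 0.45, SNAI2 at -0.79 and CCND1 at -0.11, and of the 5 genes only RNF182 passed (1.39, adjusted p = 0.0353). The count of 5 was 4 with the replicate block and 0 by limma fitted to the 4 groups alone (1357 at an unadjusted p under 0.05). It became 428 without both GFP replicate 1 arrays, 130 and 173 without the ethanol or the DHT one alone, and 1 and 2 without the ethanol or the DHT array of GFP replicate 2. It became 13 and 12 without the ethanol array of cyclin D1b replicate 1 or its DHT array of replicate 2. It became 0 by limma (1407 to 1784 genes at an unadjusted p under 0.05) without the DHT array of GFP replicate 3, the ethanol array of cyclin D1b replicate 2 or 3, or its DHT array of replicate 1 or 3. Between cyclin D1a and GFP cells limma called 0 genes (726 at an unadjusted p under 0.05). The smallest p values belonged to SNAI2 (-0.92 ± 0.189), VHL, a tumour suppressor and ubiquitin ligase subunit (-0.91 ± 0.189), and GINS4, a replisome subunit (-0.92 ± 0.199), each with an adjusted p of 1. FKBP5 (-0.39), KLK3 (0.14), TMPRSS2 (-0.09) and CCND1 (-0.13) did not pass there. In GFP replicate 1 alone, numbered in the other set, the DHT responses of SNAI2, VHL, GINS4 and FKBP5 were 1.27, 0.20, 0.65 and 1.30. In cyclin D1a cells they were -0.02, -0.54, -0.35 and 0.20. Against GFP replicates 2 and 3 alone, numbered in the same set, limma again called 0 genes (1414 at an unadjusted p under 0.05), with FKBP5 at -0.037, KLK3 at 0.34, TMPRSS2 at 0.061, CCND1 at 0.041 and SNAI2 at -0.73. The S phase list responded less in cyclin D1a than in GFP cells by a median of -0.22, with 5 of 45 members lower when adjusted over the list alone and adjusted p = 0.269 with an estimated correlation. Its median within that set was -0.11, and that of the androgen-induced list 0.019 against -0.11 pooled.

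Between both cyclins, 69 genes differed in their DHT response, 64 with a larger value in cyclin D1b cells. They included F5 (2.32 ± 0.346), EAF2 (1.59 ± 0.324), AZGP1 (1.55 ± 0.233), FKBP5 (1.48 ± 0.251, adjusted p = 0.0145) and GNB4, a G protein subunit (1.45 ± 0.308). Lower values were found for MECOM, a transcription factor (-0.79 ± 0.158), PLEKHG1, a guanine exchange factor (-0.78 ± 0.159), the tumour antigen PRAME (-0.61 ± 0.11), RSPH9, a radial spoke protein (-0.55 ± 0.114), and the kinase PLK2 (-0.55 ± 0.112). KLK3 (0.36), TMPRSS2 (0.85), SNAI2 (0.50) and CCND1 (0.35) did not pass. For TMPRSS2 the adjusted p ranged from 0.000557 to 0.626 over all alternatives, so its call depended on the setting. The S phase list differed by a median of 0.49 with 8 of 45 members passing (29 adjusted over the list alone), and kept its call at adjusted p = 0.0409 with an estimated correlation. The androgen-induced list, at a median of 0.47 with 6 of 37 members (16 adjusted over the list alone), lost it at 0.0564. The count of 69 fell to 15 and 11 without the ethanol array of cyclin D1a replicate 2 or 3, to 13, 24 and 17 without its DHT arrays of replicates 1, 2 and 3. It fell to 22 and 11 without the ethanol arrays of cyclin D1b replicates 2 and 3, and to 24, 38 and 19 without its DHT arrays of replicates 1, 2 and 3. With the mean of a gene's probe sets EAF2 (0.59, adjusted p = 0.12), GNB4 (0.59, adjusted p = 0.108) and MECOM (-0.23, adjusted p = 0.402) lost their calls. With the replicate block the count was 62, and RSPH9 and PLK2 lost theirs (0.0639 and 0.0617). Over all alternatives the adjusted p ranged from 0.000438 to 0.141 for EAF2, from 0.000224 to 0.167 for GNB4 and from 0.0086 to 0.402 for MECOM. It ranged from 0.0161 to 0.139 for RSPH9 and from 0.0156 to 0.149 for PLK2. F5 and AZGP1 kept their calls without each array. Those of EAF2, GNB4, MECOM, PLEKHG1, PRAME, RSPH9 and PLK2 were each lost without 7 or more of the 12 arrays in turn, and that of FKBP5 without 5 (adjusted p = 0.0545 to 0.0637). The DHT responses in GFP replicate 1, and in GFP replicates 2 and 3, were 2.08 and 0.67 for F5 and 1.26 and 0.38 for EAF2. They were 1.60 and 0.48 for AZGP1, 1.30 and 0.24 for FKBP5 and 1.54 and 0.065 for GNB4. Of the lower genes, MECOM (-0.30 and -0.078) and PLK2 (-0.29 and -0.089) differed the same way as between the cyclins, and PLEKHG1, PRAME and RSPH9 the other way.

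The size of the response was also compared over the genes that changed in the mean of the 3 DHT responses, which weighs the viruses equally. The genes were chosen on the same arrays, and a strong response in a single virus can bring a gene in. The medians and p values below are therefore partly set by that choice. The 653 genes that rose in that mean had median log2 changes of 0.24 in GFP, 0.13 in cyclin D1a and 0.50 in cyclin D1b cells. For these, fry gave adjusted p = 0.00752 for cyclin D1b against GFP, 0.221 for cyclin D1a against GFP and 0.0015 for both cyclins against each other. The fry p values of response size were adjusted over the rising genes, the falling genes and the androgen-induced list together. For that list they were 0.0138 for cyclin D1b against GFP and 0.00425 for both cyclins against each other. In the GFP pair of replicate 1 the median over these genes was 0.38, and in GFP replicates 2 and 3 it was 0.155 and 0.183. The 416 genes that fell had medians of -0.32, -0.14 and -0.33, with fry adjusted p = 0.588 for cyclin D1b and 0.00245 for cyclin D1a, each against GFP. The count of 1069 became 701 without the DHT array of cyclin D1a replicate 2 and 1712 without both GFP replicate 1 arrays.

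Cyclin D1a in ethanol was compared with GFP to find the genes that the full-length cyclin moved without androgen. The CCND1 probe set used here was higher, going from 9.67 ± 0.191 to 12.22 ± 0.435 (SD, n = 3), a difference of 2.55 ± 0.175 (adjusted p = 9.7e-09), while the second CCND1 probe set was lower by -0.88 ± 0.166. HSPA6, a stress-inducible HSP70, was higher by 5.30 ± 0.34 (3.18 ± 0.325 by its second probe set), and CRYAB, a small heat shock protein, by 2.47 ± 0.196. The other largest rises were in genes of cell division: the kinesin KIF18A (2.63 ± 0.232), CEP55, a factor of abscission (2.54 ± 0.234), the spindle pole gene ASPM (2.52 ± 0.313), SHCBP1 (2.51 ± 0.202) and the kinetochore scaffold KNL1 (2.44 ± 0.222). All 36 mitosis genes were higher (36 adjusted over the list alone; median 1.91), with CCNB1 at 1.86 and AURKA at 1.99. So were 43 of 45 S phase genes (43 adjusted over the list alone; median 1.405), with RRM2 at 1.89, TYMS at 1.67 and MCM2 at 1.48. Of 19 p53 targets 11 were higher and 2 lower (11 and 2 adjusted over the list alone; median 0.56), among them the CDK inhibitor CDKN1A (1.78 ± 0.147), the death receptor FAS (1.60) and DDB2 (1.27), with TP53INP1 at -0.95. Genes of the amino acid response driven by ATF4 were higher in 17 of 25 cases (18 adjusted over the list alone; median 0.37), and heat shock genes in 11 of 14 (12 adjusted over the list alone; median 0.43). These 5 lists kept their camera calls with an estimated correlation (adjusted p = 0.00499, 0.0027, 0.0223, 0.0392 and 0.0406, in the order given). The largest falls were in ABAT, GABA transaminase (-2.12 ± 0.284), CD274, which encodes PD-L1 (-1.92 ± 0.355), the glutamate receptor GRIK1 (-1.85 ± 0.42) and the hormone-responsive GREB1 (-1.78 ± 0.427). They were followed by the kinase DAPK1 (-1.74 ± 0.289), DAB1 (-1.72 ± 0.25), SMCO3 (-1.64 ± 0.502, adjusted p = 0.0289) and the protocadherin PCDHB14 (-1.61 ± 0.351). KLK3 was lower by -1.02 ± 0.119 and TMPRSS2 by -0.999 ± 0.223, SNAI2 was higher by 1.00 ± 0.134 (adjusted p = 3.25e-05), and FKBP5 did not pass (0.27 ± 0.177), though it did with the mean of its probe sets (0.504, adjusted p = 0.0225; 0.0225 to 0.572 over all alternatives). Of 37 androgen-induced genes 15 were lower and 2 higher (16 and 2 adjusted over the list alone; median -0.31), and this call was lost at adjusted p = 0.418 with an estimated correlation. The androgen-repressed list was lower too, with medians of -0.45 against GFP replicate 1 and -0.48 against replicates 2 and 3. Limma called 3550 genes, 1311 higher and 2239 lower, 1211 of them by at least 1.5-fold, and the groups did not overlap for 32.3% of genes, where chance gives 10%. Against GFP replicates 2 and 3 alone, numbered in the same set, 3599 genes passed, with CCND1 at 2.47, HSPA6 at 5.44, KIF18A at 2.32, ASPM at 2.00, SNAI2 at 0.94, KLK3 at -1.05 and TMPRSS2 at -0.77. The mitosis median was 1.75 and the S phase median 1.31. Falls were smaller there in ABAT (-1.75), CD274 (-1.45), GRIK1 (-1.20), GREB1 (-1.18) and SMCO3 (-0.78). The count was 2063 in a fit to the 6 arrays compared, and SMCO3 lost its call without the ethanol array of GFP replicate 1 (adjusted p = 0.14) or of cyclin D1a replicate 1, 2 or 3 (0.0645 to 0.0796).

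With DHT present, cyclin D1a cells again differed from GFP cells in CCND1 (2.43 ± 0.175, with the second probe set at -0.60 ± 0.166), HSPA6 (4.39 ± 0.34, with the second probe set at 2.56 ± 0.325) and genes of cell division. ASPM was higher by 2.71 ± 0.313, KNL1 by 2.55 ± 0.222, KIF18A by 2.47 ± 0.232, the mitotic kinesin KIF11 by 2.45 ± 0.292, the spindle protein gene DLGAP5 by 2.44 ± 0.264 and CEP55 by 2.42 ± 0.234. All 36 mitosis genes (36 adjusted over the list alone; median 1.94) and 42 of 45 S phase genes (43 adjusted over the list alone; median 1.03) were higher, both with adjusted p = 0.00271 with an estimated correlation. Genes of the p53 list were higher in 9 and lower in 2 of 19 cases (11 and 2 adjusted over the list alone; median 0.26), with CDKN1A at 1.75. Heat shock genes were higher in 7 of 14 (12 adjusted over the list alone; median 0.37), the latter at adjusted p = 0.0688 with an estimated correlation. LINC00844 was lower by -2.51 ± 0.657 (adjusted p = 0.0157), ABAT by -2.12 ± 0.284, GREB1 by -1.92 ± 0.427, CD274 by -1.69 ± 0.355, TRPM8 by -1.59 ± 0.215 and the transcription factor MAF by -1.53 ± 0.293. ALDH5A1, the enzyme after ABAT in GABA breakdown (-1.45 ± 0.169), and the relaxin gene RLN1 (-1.44 ± 0.208) were lower as well. KLK3 was lower by -0.88 ± 0.119 and TMPRSS2 by -1.09 ± 0.223 (adjusted p = 0.0027), whereas SNAI2 (0.08 ± 0.134) and FKBP5 (-0.12 ± 0.177) did not pass. Of 37 androgen-induced genes 17 were lower and 2 higher (23 and 2 adjusted over the list alone; median -0.42), a call lost at adjusted p = 0.186 with an estimated correlation. Limma called 2524 genes, 1109 higher and 1415 lower, 881 by at least 1.5-fold, with 34.0% of genes not overlapping, where chance gives 10%. Against GFP replicates 2 and 3 alone, 2756 genes passed, with the androgen-induced median at -0.22, KLK3 at -0.71, TMPRSS2 at -0.71, LINC00844 at -1.38, FKBP5 at 0.22, SNAI2 at 0.21 and the mitosis median at 1.90. The count was 1672 without the DHT array of GFP replicate 1, and 1551 and 1538 without the DHT array of cyclin D1a replicate 1 or 3, and LINC00844 lost its call without any of these 3 (adjusted p = 0.0571, 0.0522 and 0.0527).

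**Figure D2:**
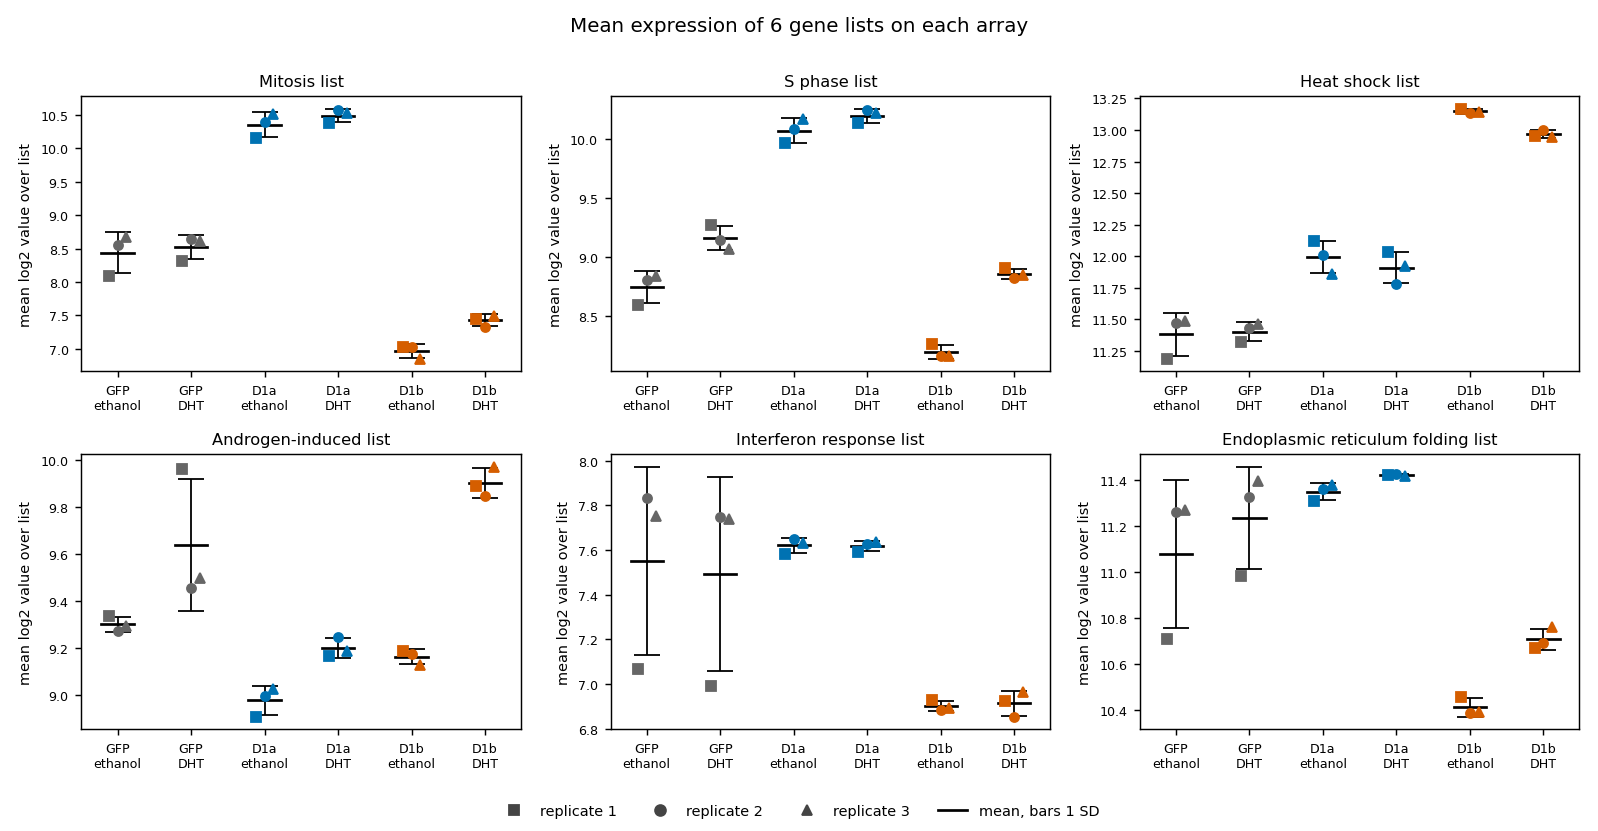
Mean log2 expression over 6 of the gene lists on each of the 18 arrays, by virus and stimulus, with points for replicates 1, 2 and 3, a line at the group mean and bars of 1 SD. Mitosis genes lay above the GFP level in cyclin D1a and below it in cyclin D1b cells, and heat shock genes were highest in cyclin D1b cells, with median differences from GFP in ethanol of 1.91, -1.55 and 1.31.

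The same comparison for cyclin D1b in ethanol gave the largest count of changed genes against GFP. HSPA6 was at 14.43 ± 0.0205 against 5.36 ± 0.24 (SD, n = 3), a log2 difference of 9.07 ± 0.34 (adjusted p = 7.16e-13), and its second probe set gave 7.48 ± 0.325. The GFP level lay below the array medians and the cyclin D1b level near the highest gene on those arrays (14.80 to 14.82), so these are differences of signal that give no exact size in transcript. The next largest rises were in ATF3, a stress-induced transcription factor (4.12 ± 0.18), BASP1 (3.91 ± 0.235), KLF4, a zinc finger factor (3.86 ± 0.0997), and IER5 (3.84 ± 0.169). SIPA1L2 (3.78 ± 0.1), the netrin NTN4 (3.75 ± 0.19) and ZFAND2A, a regulator of the proteasome (3.68 ± 0.119), came after them. SNAI2 was higher by 3.65 ± 0.134 (adjusted p = 5.49e-13), from 4.94 ± 0.241 to 8.59 ± 0.0982 (SD, n = 3). All 14 heat shock genes were higher (14 adjusted over the list alone; median 1.31), with DNAJB1 at 3.48, SERPINH1 at 3.46 and BAG3 at 2.86. So were 14 of 19 p53 targets, against 2 lower (14 and 2 adjusted over the list alone; median 0.65), with GADD45A at 2.27, CDKN1A at 2.22 and PLK2 at 2.20. The largest falls were in DLGAP5 (-2.95 ± 0.264), the antisense RNA PEG3-AS1 (-2.88 ± 0.223), the neuropeptide gene NMU (-2.66 ± 0.209) and IFIT1, an interferon-induced RNA-binding protein (-2.65 ± 0.552). They were followed by CBX5, heterochromatin protein 1 alpha (-2.63 ± 0.298), the kinesin KIF20A (-2.49 ± 0.101), the mitotic kinase NEK2 (-2.38 ± 0.233) and the deiodinase DIO1 (-2.30 ± 0.262). Mitosis genes were lower in 33 of 36 cases (33 adjusted over the list alone; median -1.55) and S phase genes lower in 32 and higher in 2 of 45 (34 and 2 adjusted over the list alone; median -0.51). Genes of secretory protein folding were lower in 17 and higher in 1 of 26 cases (18 and 1 adjusted over the list alone; median -0.64), with MANF at -1.89 and, on the other side, the unfolded protein sensor ERN1 at 1.47. Interferon response genes were lower in 19 and higher in 1 of 32 (21 and 1 adjusted over the list alone; median -0.52), with ISG15 at -1.71. None of the 10 camera calls in this comparison was kept with an estimated correlation, where adjusted p = 0.0593 for heat shock, 0.0593 for p53 targets, 0.137 for mitosis, 0.211 for S phase, 0.282 for secretory folding and 0.43 for interferon. CCND1 was lower by -1.19 ± 0.175 and its second probe set by -1.06 ± 0.166. Where these probe sets lie in the transcript is not known here, so the level of the cyclin D1b transgene cannot be read from them. KLK3 was lower by -0.79 ± 0.119 and TMPRSS2 by -0.67 ± 0.223 (adjusted p = 0.0224) by the probe sets used here. With all probe sets tested, another KLK3 probe set was called lower (-1.01 ± 0.137, adjusted p = 1.96e-05). The last KLK3 probe set did not pass (-0.14 ± 0.147, adjusted p = 0.524). For TMPRSS2, a probe set below the array medians was called lower (-0.64 ± 0.109, adjusted p = 0.000187). The remaining TMPRSS2 probe sets did not pass (-0.36 ± 0.195 and -0.04 ± 0.137, adjusted p = 0.181 and 0.877). FKBP5 was lower by -0.50 ± 0.177 (adjusted p = 0.0324). The mean of its probe sets gave FKBP5 -0.21 (adjusted p = 0.267; 0.0001 to 0.267 over all alternatives). Limma called 7868 genes, 3686 higher and 4182 lower, 3303 by at least 1.5-fold, and 47.1% of genes did not overlap, where chance gives 10%. Against GFP replicate 1 alone, numbered in the same set, 7270 genes passed, with HSPA6 at 8.80, SNAI2 at 3.76, the heat shock median at 1.74 and the mitosis median at -1.13. TMPRSS2 was at -1.13, against -0.44 for replicates 2 and 3. IFIT1 was at -1.24, the interferon median at -0.13 and the secretory folding median at -0.26, against -3.35, -0.79 and -0.90 for replicates 2 and 3. TMPRSS2 lost its call without the ethanol array of GFP replicate 1 (adjusted p = 0.124) or of cyclin D1b replicate 1 or 3 (0.069 and 0.0651), and FKBP5 without the ethanol array of GFP replicate 2 or 3 or of any cyclin D1b replicate (0.0595 to 0.0832).

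**Figure D3:**
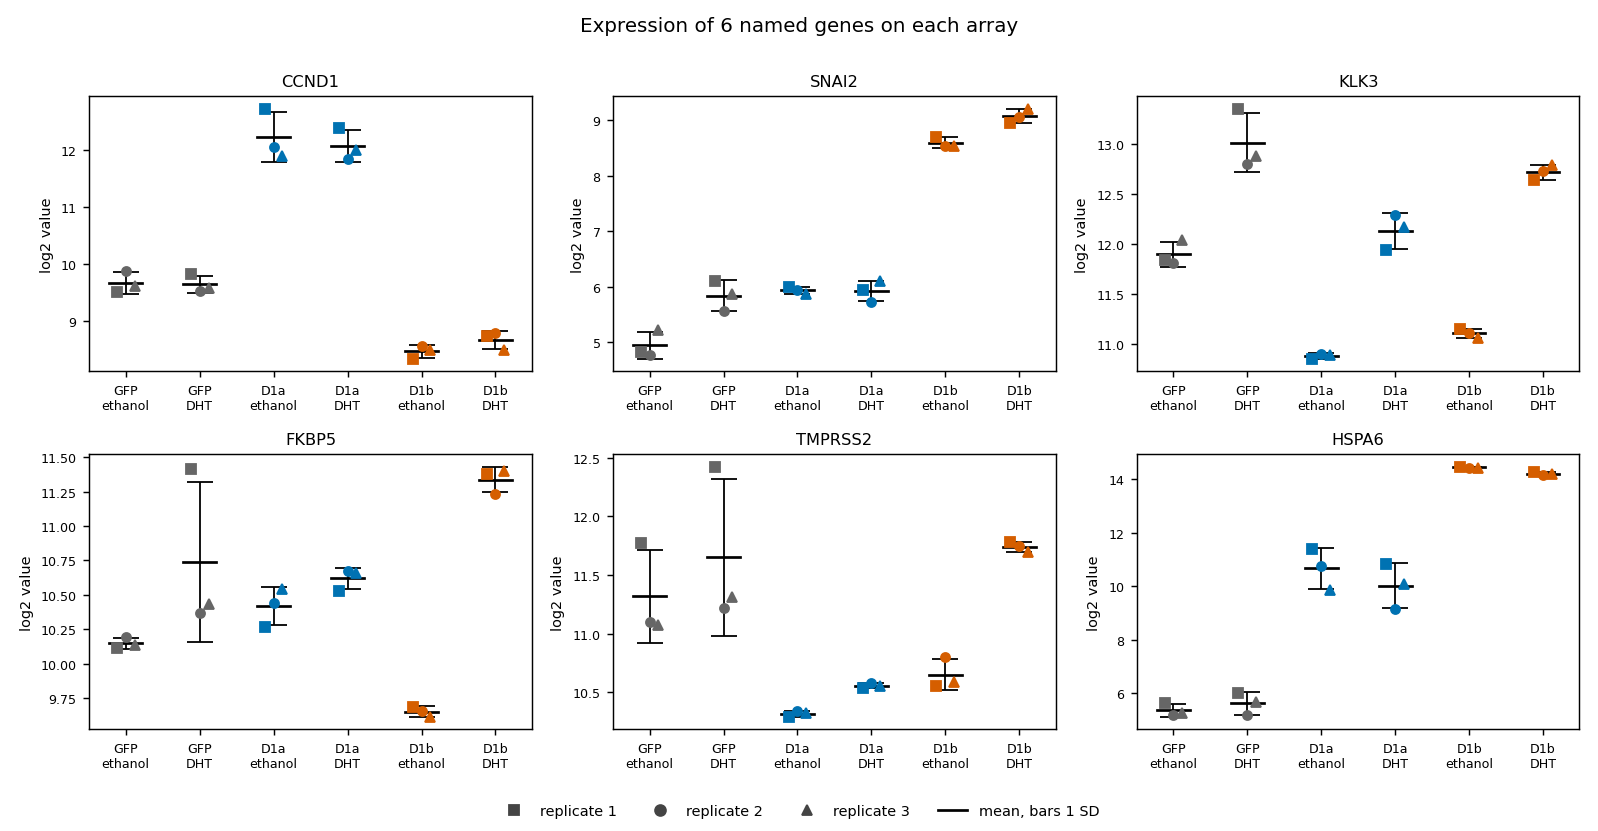
Log2 expression of CCND1, SNAI2, KLK3, FKBP5, TMPRSS2 and HSPA6 on each of the 18 arrays, by virus and stimulus, with markers for replicates 1, 2 and 3, a line at the group mean and bars of 1 SD. SNAI2 and HSPA6 were highest in cyclin D1b cells (means of 8.59 and 14.43 in ethanol), and the DHT array of GFP replicate 1 lay above both other GFP arrays for FKBP5 and TMPRSS2.

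In DHT, cyclin D1b cells kept this contrast with GFP cells. HSPA6 was higher in signal by 8.58 ± 0.34 (7.11 ± 0.325 by the second probe set), between the same ends of the scale as in ethanol. BASP1 was higher by 4.25 ± 0.235, NTN4 by 4.08 ± 0.19, ATF3 by 4.03 ± 0.18, SIPA1L2 by 3.76 ± 0.1, KLF4 by 3.68 ± 0.0997, IER5 by 3.61 ± 0.169 and ZFAND2A by 3.55 ± 0.119. SNAI2 was higher by 3.23 ± 0.134 (adjusted p = 4.14e-12). PEG3-AS1 was lower by -3.22 ± 0.223, the RNA-binding protein gene MATR3 by -3.03 ± 0.547, IFIT1 by -2.62 ± 0.552 and NMU by -2.44 ± 0.209. UGT2B15 was lower by -2.29 ± 0.21, UGT2B17 by -2.26 ± 0.168, the kinetochore gene SPC25 by -2.24 ± 0.162 and DIO1 by -2.24 ± 0.262. Mitosis genes were lower in 35 of 36 cases (35 adjusted over the list alone; median -1.07, adjusted p = 0.139 with an estimated correlation), with KIF20A at -2.02 and CCNB2 at -1.38. Heat shock genes were higher in 13 of 14 (13 adjusted over the list alone; median 1.08) and p53 targets higher in 14 and lower in 1 of 19 (14 and 1 adjusted over the list alone; median 0.67). Androgen-repressed genes were lower in 7 of 12 (7 adjusted over the list alone; median -0.62). These 3 lists kept their calls with an estimated correlation (adjusted p = 0.0467, 0.032 and 0.032). Of 37 androgen-induced genes 16 were higher and 6 lower (17 and 10 adjusted over the list alone; median 0.16), which camera did not call (adjusted p = 0.201). SGK1 stood at 1.19, ERRFI1 at 2.69 and ACP3, prostatic acid phosphatase, at -1.21. FKBP5 was higher by 0.60 ± 0.177 (adjusted p = 0.013), CCND1 lower by -0.97 ± 0.175 with the second probe set at -0.82 ± 0.166, and KLK3 (-0.30 ± 0.119, adjusted p = 0.064) and TMPRSS2 (0.09 ± 0.223) did not pass. Limma called 6694 genes, 3550 higher and 3144 lower, 2793 by at least 1.5-fold, with 41.9% of genes not overlapping, where chance gives 10%. Against GFP replicate 1 alone 5925 genes passed, with HSPA6 at 8.20, SNAI2 at 2.97, the heat shock median at 1.35, FKBP5 at -0.075, TMPRSS2 at -0.68, KLK3 at -0.63, IFIT1 at -0.88 and DIO1 at -1.43. The androgen-induced median was -0.075 there and the interferon median -0.026 (-0.46 pooled). Against replicates 2 and 3 FKBP5 was at 0.94, TMPRSS2 at 0.47, KLK3 at -0.13, IFIT1 at -3.49, DIO1 at -2.64 and the androgen-induced median at 0.40. With the replicate number as a block 6870 genes passed. The calls changed without the DHT array of GFP replicate 1 for TMPRSS2 (0.47, adjusted p = 0.0173), without that of GFP replicate 2 or 3 for FKBP5 (adjusted p = 0.0911 and 0.0847) and KLK3 (0.0213 and 0.0487).

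A direct comparison of both cyclins shows where the splice variant and the full-length protein parted, although all cyclin D1b arrays are numbered below 125 and all cyclin D1a arrays from 125 on. In ethanol, HSPA6 was higher in cyclin D1b cells by 3.77 ± 0.34 in signal, which near the top of the scale gives no exact size in transcript there or in DHT. BASP1 was higher by 3.50 ± 0.235, the stress factor MAFF by 3.34 ± 0.213, ATF3 by 3.29 ± 0.18, the nuclear receptor RORA by 3.20 ± 0.136 and SNAI2 by 2.66 ± 0.134. DLGAP5 was lower by -5.13 ± 0.264, CEP55 by -4.78 ± 0.234, the topoisomerase TOP2A by -4.55 ± 0.172, NEK2 by -4.55 ± 0.233, KIF20A by -4.32 ± 0.101 and CCND1 by -3.75 ± 0.175, a fall that the second CCND1 probe set did not show (-0.18 ± 0.166, adjusted p = 0.442). All 36 mitosis genes (36 adjusted over the list alone; median -3.49) and 43 of 45 S phase genes (43 adjusted over the list alone; median -1.77) were lower, with adjusted p = 0.0313 and 0.0225 with an estimated correlation. In DHT the mitosis median was -3.05 and the S phase median -1.26, both with adjusted p = 0.0208 with an estimated correlation. DLGAP5 was at -4.58 ± 0.264, NEK2 at -4.28 ± 0.233, SPC25 at -4.16 ± 0.162, ASPM at -4.04 ± 0.313, and CCND1 at -3.39 ± 0.175, with the second probe set at -0.22 ± 0.166 (adjusted p = 0.372). HSPA6 was at 4.19 ± 0.34 in signal, MAFF at 3.67 ± 0.213, RORA at 3.46 ± 0.136, BASP1 at 3.44 ± 0.235, NTN4 at 3.34 ± 0.19 and SNAI2 at 3.15 ± 0.134. Androgen-induced genes went both ways in ethanol, where 22 of 37 passed (13 higher and 9 lower, 13 and 10 adjusted over the list alone; median 0.10, camera adjusted p = 0.496). There KLK3 (0.23 ± 0.119) did not pass and FKBP5 was lower by -0.77 ± 0.177. The TMPRSS2 probe set used here did not pass (0.33 ± 0.223). Of its other 3 probe sets, 1 was called higher (0.46 ± 0.137, adjusted p = 0.015) and 1 did not pass (0.39 ± 0.195, adjusted p = 0.134). The third was called lower (-0.47 ± 0.109, adjusted p = 0.00249), with means of 4.76 in cyclin D1b and 5.23 in cyclin D1a cells, below the array medians. With the label number set as a term the probe set used here was at -0.59 (adjusted p = 0.00109; 0.00109 to 0.477 over all alternatives). In DHT 24 were higher and 1 lower (24 and 1 adjusted over the list alone; median 0.58, lost at adjusted p = 0.297 with an estimated correlation), and KLK3 at 0.58 ± 0.119, TMPRSS2 at 1.18 ± 0.223 and FKBP5 at 0.72 ± 0.177 all passed. The mean of its probe sets gave FKBP5 0.29 (adjusted p = 0.136; 3.49e-05 to 0.441 over all alternatives). Limma called 8024 genes in ethanol, 4486 higher and 3538 lower, and 7111 in DHT, 4243 higher and 2868 lower. With the label number set as a term, estimated from the GFP arrays, the DHT values of KLK3, TMPRSS2 and FKBP5 were 0.37, 0.26 and 0.24 and no longer passed (adjusted p = 0.0864, 0.143 and 0.441). The matrix metalloproteinase MMP7, lower in cyclin D1b cells in DHT by -4.15 ± 1.15, was at 1.00 in that fit. Its level was 5.44 to 6.06 on all arrays numbered below 125 and 9.69 to 10.81 on all others.

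Both cyclins were compared with the same 3 GFP arrays, so their overlap was set against simulations of unchanged groups with those controls, which cannot be split into separate sets of 3. In ethanol 405 genes were higher with both cyclins (244 expected from n1 × n2 / N) and 1102 lower with both (474 expected). By contrast 451 were higher with cyclin D1a and lower with cyclin D1b (277 expected) and 240 the reverse (417 expected). In DHT the counts were 384 (199 expected), 619 (225), 295 (176) and 152 (254), in the same order. The log2 fold changes of the cyclins correlated across genes, which are not independent replicates, at 0.125 in ethanol and 0.137 in DHT. Unchanged groups with shared controls gave 0.499 in 100 simulations for each stimulus. Real changes widen the spread of the fold changes and the simulated groups hold none, so 0.499 is no measure for these correlations. The covariance of the cyclins' fold changes was 0.0203 and 0.0186 against 0.00697 and 0.00698 simulated. The simulations gave all groups the same spread for a gene, while GFP replicate 1 stood apart, so shared controls may give more covariance than simulated. The simulations shared 0 calls, which unchanged groups fix in advance, so this is no measure for the counts above. The responses to DHT share no arrays: 30 of the 32 genes that rose in GFP cells also rose in cyclin D1b cells (1.43 expected), and 31 of the 55 that fell also fell (0.773 expected).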

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

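Tests of a separate or shared batch for GFP replicate 1, of a shared batch for the heat shock genes and for the DHT response, and the jackknife SE over arrays, were chosen after the result was seen.

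Some DHT responses differed between viruses by a test of the difference itself. Between cyclin D1b and GFP cells, 5 genes differed: RNF182 (1.08), GPER1 (1.01), OTULINL (0.99), LSM11 (0.92) and PRCP (0.84). The list medians of that difference were 0.39 for androgen-induced, 0.28 for S phase, 0.38 for mitosis, 0.21 for cholesterol synthesis, 0.23 for fatty acid synthesis and -0.18 for heat shock genes. Between cyclin D1b and cyclin D1a cells, whose arrays lie in different sets of label numbers, 69 genes differed, among them F5 (2.32), EAF2 (1.59), AZGP1 (1.55), FKBP5 (1.48), GNB4 (1.45), MECOM (-0.79), PLEKHG1 (-0.78), PRAME (-0.61), RSPH9 (-0.55) and PLK2 (-0.55). The list medians there were 0.47 for androgen-induced, -0.24 for androgen-repressed, 0.49 for S phase, 0.37 for mitosis, 0.24 for cholesterol synthesis, 0.24 for fatty acid synthesis, 0.25 for secretory folding and 0.11 for hypoxia genes. Between cyclin D1a and GFP cells, the medians were -0.11 for androgen-induced, -0.22 for S phase, -0.11 for cholesterol synthesis and -0.068 for ribosome biogenesis genes. With an estimated correlation camera called none of the lists between either cyclin and GFP (adjusted p = 0.344 for all 6 lists of cyclin D1b), and 3 of the 8 between both cyclins.

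Probe sets without a single gene symbol, 13522 in all and outside the gene tests, also changed. The count was 10 for DHT in GFP cells, 1037 and 586 for cyclin D1a against GFP in ethanol and DHT, and 3172 and 2781 for cyclin D1b.

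Androgen-induced genes responded more to DHT in cyclin D1b than in GFP cells, by a median of 0.39, a list call that was lost with an estimated correlation (adjusted p = 0.344) and by fry (0.0673). The unlike GFP replicate 1 as the cause is argued against, since without it the median was 0.55 (SE 0.0659 by jackknife over arrays, 0.0663 by bootstrap over the list's genes). A lower starting level cannot be told apart: 15 members not lower in cyclin D1b cells in ethanol had a median of 0.23, above 0 by more than its bootstrap SE over genes (0.102), which leaves out the spread between arrays, but not by more than 2 jackknife SEs over arrays (0.221). The ethanol values that chose these members also enter the difference between responses, which pushes their median down by construction. A batch shared by GFP replicate 1 and the cyclin D1b arrays may account for part of it: against that replicate alone the median was 0.16 (bootstrap SE over genes 0.0637, with no spread to be had from 1 GFP array per stimulus). An effect of cyclin D1b on androgen signalling remains open beside these.

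Heat shock genes were higher in cyclin D1b than in GFP cells in ethanol, by a median of 1.31, a camera call lost with an estimated correlation (adjusted p = 0.0593) and kept by fry (1.33e-09). RNA degradation is argued against, as 5 of the 6 cyclin D1b arrays lay at or below the highest GFP array (0.764) in the 3' minus 5' difference. The median was at least 1.29 after rescaling, which cannot decide on normalization. Array medians and quantiles already lay close together, so rescaling could change little. A batch shared with GFP replicate 1 is argued against, as that replicate had a score -0.21 from the other GFP arrays (mean of both stimuli, SD 0.116), where the cyclin D1b arrays had 1.67. A batch of the cyclin D1b arrays alone cannot be told apart from the virus. That cyclin D1b itself induced the genes is a hypothesis found and tested on the same data, and a difference between virus preparations, which the labels say had equal titers, was not tested.

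Both GFP replicate 1 arrays stood apart. RNA degradation cannot be told apart from other causes: the lower of their 3' minus 5' differences was 0.706, above the other 4 GFP arrays and below 1 cyclin D1b array at 0.812. A separate culture or array batch cannot be told apart either: both deviated alike (correlation across genes 0.662, against 0.428 and 0.520 for replicates 2 and 3 and at most 0.0198 within the cyclin cells), which restates the pattern and favours no cause. A batch shared with the cyclin D1b arrays is a candidate explanation, since their deviation correlated at 0.372 with the difference between cyclin D1b and cyclin D1a, against 0.0614 for GFP replicate 2 against 3. No biological explanation was tested.

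Other splits of the same arrays were counted for each comparison. The 10 splits of 3 against 3 are too few for a share under 0.05. For DHT in GFP cells 4 of the 10 splits, the real one included, called at least as many genes as the real 87, and the highest other called 964. The splits that keep both replicate 1 arrays on 1 side called 509, 964, 362 and 4, which points to a structure of the samples, and the count without both of those arrays was 169. The real split parts all 3 replicate numbers, and the 3 other splits that do so called 0 genes by limma, where the real split had 1919 genes at an unadjusted p under 0.05. In each other comparison of 3 against 3 only the real split, 1 of 10, called as many. The real counts and the highest others were 2 and 0 for DHT in cyclin D1a cells, 1161 and 4 for DHT in cyclin D1b cells, 3550 and 1 for cyclin D1a in ethanol, 7868 and 0 for cyclin D1b in ethanol, 2524 and 0 for cyclin D1a in DHT, and 6694 and 1 for cyclin D1b in DHT. For both cyclins against each other they were 8024 and 0 in ethanol and 7111 and 0 in DHT. Chance was not excluded for 2 differences between responses: 7 of 100 drawn splits reached the 5 genes of cyclin D1b against GFP (highest other 1251) and 12 of 100 the 69 of both cyclins (582). For cyclin D1a against GFP, with 0 genes by limma (726 at an unadjusted p under 0.05), all 100 splits reach that count by construction (highest other 5), so this says nothing about chance. Splits that called 1251 and 582 genes point to a structure of the samples. The splits were drawn within each virus whatever the replicate number, so splits with both GFP replicate 1 arrays on 1 side were not left out. The share for cyclin D1b against GFP therefore does not measure chance alone. For the mean DHT response 1 of 100 splits, the real one, reached 1069 genes (highest other 541), a share under 0.05. A smaller share cannot be seen with 100 splits, so chance is made unlikely and not excluded.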

How the results depend on the processing

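Blocks within each virus, the label number set as a term, and GFP replicate 1 as the only GFP arm were chosen after the data had been seen. All 13 counts of changed genes stayed within 1.5 times their value with median centring, with trend and robust variance, and with a replicate block (75 for DHT in GFP cells, from 87). Of the named genes' values, 178, 177 and 180 of 184 kept direction and side of the threshold there. Camera with an estimated correlation kept 32 of 115 list calls and fry 87. For the values below the cause was not tested, except that fits to fewer arrays, or to more probe sets, change the number tested.

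With all probe sets tested, the counts were 50 for DHT in GFP, 7 for DHT in cyclin D1a, 6372 and 4017 for cyclin D1a against GFP in ethanol and DHT, 17072 and 14918 for cyclin D1b, 18279 and 16162 between both cyclins, and 37 for the difference between their responses. With the mean of a gene's probe sets, DHT in GFP gave 37, the difference between cyclin D1b and GFP responses 14, and the NF-kB median for cyclin D1b in DHT was -0.015. The upper part of genes by mean gave 172 for DHT in GFP, and quantile normalization again gave 3 for the difference between cyclin D1b and GFP responses.

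In fits to only the groups compared, limma called 0 genes for DHT in GFP (990 at an unadjusted p under 0.05), 7 for DHT in cyclin D1a, 2063 for cyclin D1a in ethanol, 0 for the difference between cyclin D1b and GFP responses (1357 unadjusted) and 311 for that between both cyclins. A block within each virus gave 280, 4 and 1853 for DHT in GFP, cyclin D1a and cyclin D1b, 10 and 124 for those differences, and 1723 for the mean response.

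With the label number set as a term, DHT gave 486, 6 and 2243 genes in GFP, cyclin D1a and cyclin D1b and 2099 in the mean, and the differences gave 1 for cyclin D1a, 104 for cyclin D1b and 284 between them. TMPRSS2 reversed to -0.53 for cyclin D1b in DHT and -0.59 between both cyclins in ethanol, MMP7 to 1.00 between both in DHT, the ribosome biogenesis median to 0.026 for cyclin D1b in DHT, and the interferon median to 0.091 and 0.068 between both in ethanol and DHT. With GFP replicate 1 alone, counts were 352 for DHT in GFP, 54 for the cyclin D1a difference, and 5614 and 4538 for cyclin D1a in ethanol and DHT. There TMPRSS2 (-0.68) and FKBP5 (-0.075) reversed for cyclin D1b in DHT, the androgen-repressed median (0.079) for cyclin D1a in DHT, and the S phase (-0.0010) and fatty acid (-0.071) medians for the cyclin D1b difference. At a threshold of 0.01, 759 genes in ethanol (from 1507) and 445 in DHT (from 1003) changed alike with both cyclins.

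With arrays left out, counts ranged from 36 to 248 for DHT in GFP (lowest without its DHT array of replicate 2, highest without its ethanol array of replicate 1), from 567 to 1136 in cyclin D1b, from 1538 to 2756 for cyclin D1a in DHT, from 0 to 428 for the cyclin D1b difference, from 11 to 85 between both cyclins, and from 701 to 1712 for the mean. They ranged from 2469 to 3752 for cyclin D1a in ethanol, from 6782 to 8416 and 5680 to 7695 for cyclin D1b, and from 6823 to 7580 and 5986 to 6691 between both cyclins. List medians for DHT in GFP ranged from -0.050 to 0.21 for mitosis and from -0.030 to 0.28 for secretory folding genes, both lowest without the ethanol array of GFP replicate 1, where fatty acid genes had -0.019. Fatty acid genes ranged from -0.087, without both GFP replicate 1 arrays, to 0.14. For the cyclin D1a difference the androgen-induced median ranged from -0.20 to 0.049, the latter without the DHT array of GFP replicate 1. The ribosome biogenesis median ranged from -0.12 to 0.054, the latter without both GFP replicate 1 arrays.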

Other observations

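The genes singled out by a gap between sets of label numbers, at the end of this part, were chosen after their values were seen.

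The lists of invasion and adhesion genes and of G1 regulators, which camera did not call for cyclin D1b against GFP in ethanol, held members that moved both ways. In ethanol the chemokine receptor CXCR4 was higher by 2.35 ± 0.171, the protease inhibitor SERPINE2 by 2.30 ± 0.153 and the sheddase ADAM17 by 1.58 ± 0.0942, and in DHT by 1.96, 2.20 and 1.399 (SE as before, n = 3 arrays per group). The integrin ITGA6 was lower in ethanol by -0.66 ± 0.129. Invasion and adhesion genes were higher in 6 and lower in 6 of 28 cases (6 and 6 adjusted over the list alone; median 0.00, and 0.076 against GFP replicate 1 alone). The CDK inhibitor CDKN2B was higher by 2.52 ± 0.176 in ethanol and 2.78 ± 0.176 in DHT, and MYC lower by -0.73 ± 0.0872 and -0.92 ± 0.0872. Regulators of G1 were higher in 5 and lower in 7 of 22 cases in ethanol (5 and 8 adjusted over the list alone), with a median of -0.15 and a mean of 0.02, which differ in sign, and camera gave adjusted p = 0.381. With cyclin D1a the same list was higher in 9 and lower in 1 (9 and 2 adjusted over the list alone; median 0.14, adjusted p = 0.00339 with an estimated correlation), with CDC25A at 1.22 and CDK2 at 0.99. CCND1, the gene that this virus carries, was among the higher members (2.55), and the list was not tested without it.

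Mesenchymal genes other than SNAI2 moved both ways with cyclin D1b in ethanol. The proteoglycan LUM was higher by 1.77 ± 0.189 and smooth muscle actin ACTA2 by 1.71 ± 0.204, and fibronectin FN1 was lower by -1.18 ± 0.239. Of 24 mesenchymal genes 7 were higher and 3 lower (9 and 3 adjusted over the list alone; median 0.16, camera adjusted p = 0.0631), and fry gave adjusted p = 4.8e-08. Epithelial junction genes were lower in 10 and higher in 3 of 25 (13 and 3 adjusted over the list alone; median -0.18, camera adjusted p = 0.0631), with the claudin CLDN3 at -0.70 and the splicing regulator ESRP1 at 0.99. Against GFP replicate 1, numbered in the same set, the junction median was -0.056, and against replicates 2 and 3 it was -0.30. Inflammatory genes TNFAIP3 (1.65 ± 0.084), NFKBIZ (1.60 ± 0.128), LIF (1.15 ± 0.0927) and CXCL2 (1.11 ± 0.0996) were higher, 8 of 21 in the NF-kB list with 1 lower (8 and 1 adjusted over the list alone; median 0.10, and 0.17 against GFP replicate 1, adjusted p = 0.211 with an estimated correlation).

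The hypoxia list held members on both sides in ethanol, with hexokinase HK2 at -1.88 ± 0.13 and the demethylase KDM3A at 1.53 ± 0.109. It was lower in 10 and higher in 5 of 20 (10 and 5 adjusted over the list alone; median -0.24, camera adjusted p = 0.231). Fatty acid synthesis genes were lower in 8 and higher in 3 of 12 (8 and 3 adjusted over the list alone; median -0.41, and -0.23 against GFP replicate 1, camera adjusted p = 0.0827). Ribosome biogenesis genes were lower in 8 and higher in 3 of 18 (9 and 3 adjusted over the list alone; median -0.22, camera adjusted p = 0.0672), but this median was 0.12 against GFP replicate 1, numbered in the same set, and -0.33 against replicates 2 and 3. The ATF4 response was higher in 15 and lower in 2 of 25 (15 and 2 adjusted over the list alone; median 0.37, adjusted p = 0.211 with an estimated correlation), with STC2 at 1.34, DDIT3 at 1.19 and TRIB3 at 1.12.

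Marker lists of other cell types were not called by camera in ethanol for cyclin D1b. Stromal markers, which share LUM, ACTA2 and collagen genes with the mesenchymal list, were higher in 4 and lower in 1 of 14 cases (4 and 1 adjusted over the list alone; median 0.10, adjusted p = 0.157). Neuroendocrine markers had a median of 0.06 (adjusted p = 0.64; -0.014 against GFP replicate 1), basal epithelial markers -0.12 (0.79; -0.066 against it) and leukocyte and endothelial markers 0.06 (0.418).

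MMP7 lay between 5.44 and 6.06 on the 8 arrays numbered below 125 and between 9.69 and 10.81 on the other 10. Each cyclin lies in a single set of numbers, so only the GFP arrays separate the number from the virus. AKR1C2, an aldo-keto reductase, lay between 7.07 and 7.76 against 9.38 and 10.57, GBP3, a guanylate-binding protein, between 4.80 and 5.43 against 7.35 and 7.91, and LCN2, a lipocalin, between 6.52 and 7.05 against 8.63 and 9.13. The interferon-induced IFI6 lay between 6.85 and 7.68 against 9.22 and 10.03, and CCN3, a matricellular protein, was higher on the 8 arrays (7.94 to 9.42 against 5.59 to 6.47). A gap of more than 1 on the log2 scale between these sets was found for 16 lower and 4 higher genes, and for 0 genes when GFP replicate 2 or 3 took the place of replicate 1, by a comparison of ranges without a test.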
